A study of Giardia lamblia ATCC 50803 with 6 samples.

How the data were processed

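Poly(A)-selected RNA of Giardia lamblia was sequenced in 6 libraries, 3 from trophozoites labelled as arrested in G1 and 3 from trophozoites labelled as arrested in G2. Giardia lamblia is a flagellated intestinal parasite, and the trophozoite is its motile, dividing form. Libraries were made with a stranded Illumina TruSeq mRNA kit and sequenced on an Illumina instrument, per the labels' protocols and the series' design text. The extraction text of the labels names human cells as the RNA source, while the organism, strain and reference labels of every sample name Giardia, and the table analysed held Giardia genes. Each sample's group and replicate number were taken from its title.

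The submitters' processing notes name bcl2fastq 1.8.4, HISAT2 2.0.5, StringTie 1.3.3b and Cufflinks, without roles or order. The reference label names the Giardia assembly GL2, and the counting settings and the use of strand are not given in the sources used here. The authors deposited 1 table of 6582 genes with a read count and an FPKM value for each sample, per the file headers. The deposited count columns held whole numbers. For 1700 genes above 2000 counts in every sample, the ratio of a gene's count to its FPKM differed between samples by 1 factor for all genes, within 0.0605%. At low counts that proportion did not hold: for 68 genes with a count of 1 in both G1 replicates 2 and 3, the FPKM in replicate 3 was 0.122 to 51.6 times that in replicate 2. They were therefore treated as estimated counts that the authors had derived from transcript abundance and rounded, and were used as deposited. FPKM is an estimated fragment number scaled by transcript length and by the mapped fragments of the library, and the deposited FPKM values were not on a log scale. The FPKM columns summed to between 933816 and 981186, with no sign that their distributions had been made equal, although they were described as normalized. Every value column of the table belonged to 1 of the 6 samples. The table gives locus tags and product descriptions without coordinates, and no genome was used, so no positions are given.

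Total estimated counts were 20257642, 20094762 and 19610417 in G1 replicates 1 to 3 and 18220468, 20485346 and 18736955 in G2 replicates 1 to 3. At least 99.9906% of them fell in the genes tested. Genes with a mean FPKM of at least 1 over the 6 samples were tested, which kept 5909 genes, 5874 of them protein-coding and 35 noncoding.

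The test fixed before the data were examined was limma on log2(FPKM + 1), to be replaced by the edgeR quasi-likelihood test if the table held whole-number read counts. The table did, so the main test was glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, with TMM scaling, group as the only term, and Benjamini-Hochberg adjustment at 0.05. The deposited counts are estimates rather than tallied reads, and limma 3.58.1 on the FPKM values was kept as an alternative. Log2 fold changes are coded as G2 minus G1, and their standard errors (SE) were computed as the absolute log2 fold change divided by the square root of the F statistic. A second criterion required an absolute log2 fold change of at least 1. Where the text writes that a gene rose or fell, its adjusted p in this test was under 0.05.

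For 27 gene lists, members were found by matching patterns to the product descriptions. The patterns were written before the data were examined. Each list was tested with camera of limma on log2 CPM (counts scaled to a common library total with the TMM factors), with a prior count of 2 and a preset correlation of 0.01, and adjusted over the 27 lists. The encystation list also served as the marker list for encysting cells, the other cell type such a culture can hold.

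Genes were named by a rule fixed before the data were examined. Among genes with adjusted p under 0.05, an absolute log2 fold change of at least 1 and no overlap between the 3 G1 and the 3 G2 values, the 10 largest rises and 10 largest falls with an informative description were eligible, with the 2 largest each way without one. From each list, up to 4 members with the smallest adjusted p were added. Every member of the lists of cyclins and cyclin-dependent kinases, of mitotic kinases and spindle checkpoint proteins and of core histones could be given. The cyst wall proteins of the marker list lie outside this rule and are given whatever their p. Genes named outside the rule are said to have been chosen after their values were seen.

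The tests were checked on simulated counts drawn from the real means, library sizes and dispersion of the 5909 genes, with 100 genes changed 2-fold and 100 changed 1.5-fold between the groups. edgeR called 83 of the 100 genes changed 2-fold, 69 of the 100 changed 1.5-fold and 7 of 5709 unchanged genes. With a list of 30 genes raised 1.3-fold, camera recovered the list, and 1 of 100 random lists had a p under 0.05. The simulated genes were drawn without correlation between them, so this cannot show whether the preset correlation of camera is high enough for real lists. In the real data, the correlations estimated for the 5 lists that passed camera lay between -0.0226 (mitotic kinases and spindle checkpoint proteins) and 0.458 (core histones).

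Replicates were compared before they were averaged. A chi-square statistic over genes, divided by its degrees of freedom, was 8.24 for the closest pair, G1 replicates 2 and 3. It was 49.2 and 51.6 for G1 replicate 1 against these. By this measure no pair agreed to within sampling noise, and all 6 were kept as separate samples. The statistic treats the estimated counts as tallied reads, so it cannot tell technical replicates from separate cultures. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

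The alternatives fixed in advance were limma with pseudocounts of 1, 0.1 and 5, without its variance trend, after quantile normalization, after median-of-ratios scaling and with the replicate number as a block. DESeq2 1.42.0, edgeR with DESeq2-type size factors, without a filter, with a mean FPKM of at least 10 and with the replicate block, an adjusted p under 0.01, and leaving out each of the 6 samples were also fixed in advance. For lists, camera with an estimated correlation and fry were added to these. Of the alternatives chosen after the data were seen, the first left out genes whose counts differed at least 8-fold within a group, another left out tRNA and rRNA rows, and the last used library totals without scaling factors.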

Results

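Gene expression was measured by RNA sequencing in Giardia lamblia trophozoites, the motile form of this intestinal parasite, in 3 samples labelled as arrested in G1 and 3 labelled as arrested in G2. The series' design text names nocodazole, which blocks microtubule assembly, and aphidicolin, which blocks replicative DNA polymerases, while every sample title names nocodazole alone. By the titles both groups had the same drug, while the design text leaves it possible that the groups had different drugs. The sources used here do not resolve this conflict. If the drugs differed, the phase and the drug cannot be told apart in this comparison. Each library held between 18220468 and 20485346 estimated counts. The first principal component separated the groups and held 46.3% of the variance, and the second held 18.7% and set G1 replicate 1 apart from the others.

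The comparison asks which genes, and among them which cell-cycle genes, were higher in the G2-arrested cells. A cyclin-dependent kinase, cyclin B and the spindle checkpoint gene MAD2 were 2.29- to 3.03-fold higher in G2. Both H2A, both H2B and 3 of 4 H3 histone genes rose, as did 15 of 26 kinesins, the motor proteins that move along microtubules, while 5 kinesins fell. Of 81 high cysteine membrane proteins, 49 fell and 7 rose, and the 3 beta-tubulin genes fell. Of 43 chaperone genes, 13 fell, among them the abundant Bip, and 11 rose. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2032 of 5909 genes changed, 1185 of them higher and 847 lower in G2. Of these, 205 changed at least 2-fold, 110 higher and 95 lower. Higher calls made up 58.3% with TMM scaling, 43.6% with library totals and no scaling factor (924 higher, 1196 lower) and 44.0% with limma on the FPKM values as deposited (886 higher, 1129 lower). No called gene changed sign in any of these settings. For 2882 genes, 48.8%, the 3 G1 and the 3 G2 values did not overlap, where chance gives 10%.

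Cyclins and cyclin-dependent kinases drive the passage from one phase of the cell cycle to the next. The list held 12 tested genes, including regulators matched by their descriptions. Of these, 5 rose and 2 fell, and the counts adjusted over the list alone were also 5 and 2. The kinase GL50803_16802 had 199.8 ± 18.7 FPKM in G1 and 478 ± 0.783 FPKM in G2 (mean ± SD, n = 3), a log2 fold change of 1.33 ± 0.07 (SE) with an edgeR adjusted p of 4.65e-06. The G2/mitotic-specific cyclin B GL50803_3977 had 75.3 ± 8.47 FPKM in G1 and 164 ± 3.73 FPKM in G2, a log2 fold change of 1.19 ± 0.08 with an edgeR adjusted p of 1.22e-05. The regulatory subunit GL50803_2661, which binds cyclin-dependent kinases, rose by 0.81 ± 0.07 on the log2 scale. The kinase GL50803_8037 rose by 0.51, and the cyclin B-like gene GL50803_17505 by 0.50. GL50803_8432, described as APC11 and cyclin metabolism, fell 1.66-fold, a log2 fold change of -0.73 ± 0.10 with an edgeR adjusted p of 0.000738. In other eukaryotes APC11 belongs to a ubiquitin ligase that marks cyclins for destruction. Whether this Giardia gene has that role was not tested. Cyclin A GL50803_14488 fell by 0.14 with an edgeR adjusted p of 0.0413, a call that was lost without any 1 library other than G1 replicate 1 (edgeR adjusted p 0.0605 to 0.127 in those fits, 0.00432 to 0.127 over all its alternatives). The remaining kinases, GL50803_9422, GL50803_4191, GL50803_11290 and GL50803_15397, and the cyclin fold gene GL50803_93721 had log2 fold changes between -0.13 and 0.16 that did not pass. The list as a whole did not differ from the other genes (camera adjusted p = 0.270).

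**Figure D1:**
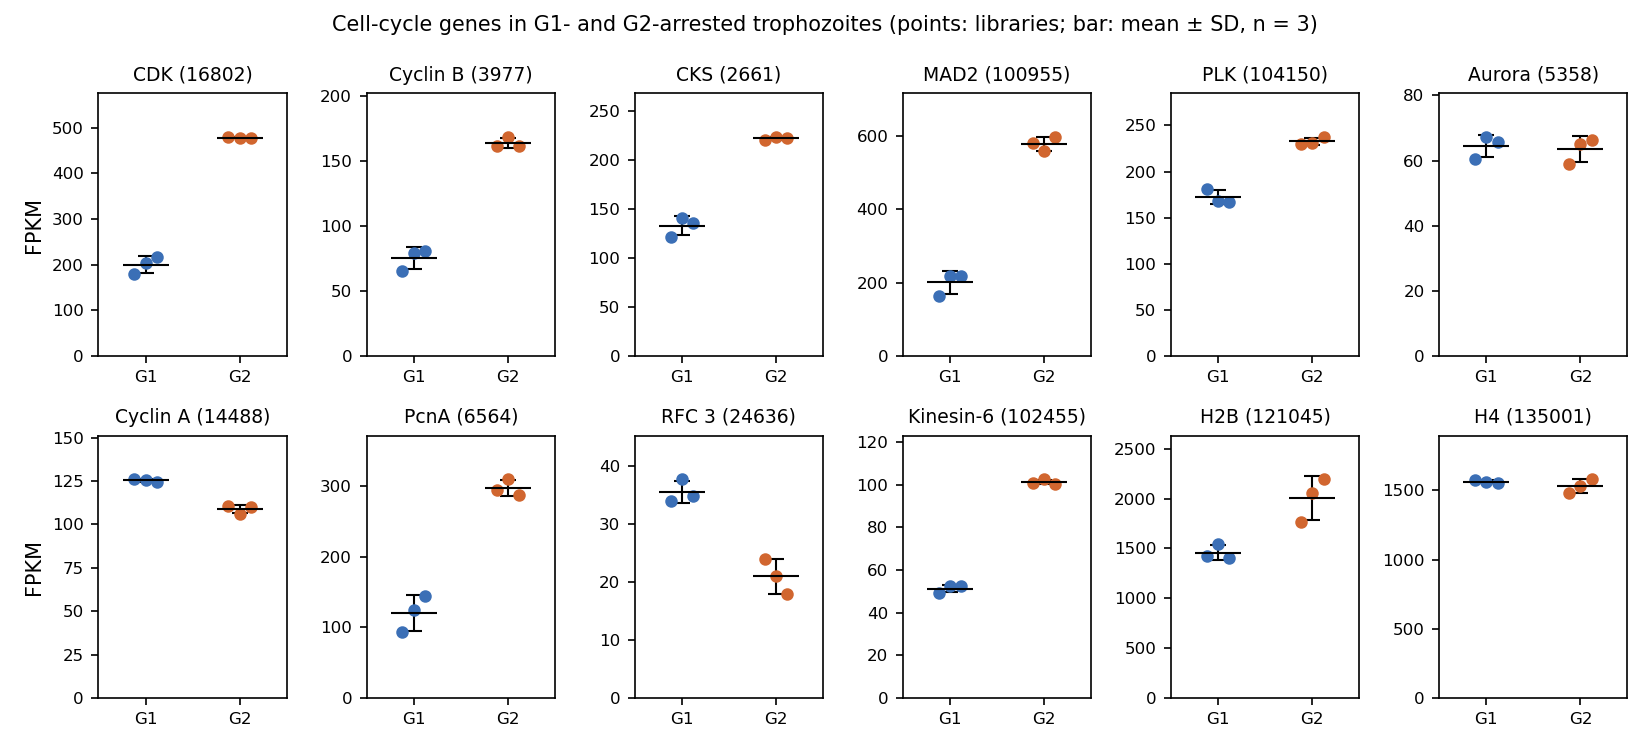
FPKM (vertical axes, starting at 0) of 12 cell-cycle genes in the 3 G1-arrested (blue) and 3 G2-arrested (orange) libraries; points are libraries and bars the mean ± SD. The kinase GL50803_16802, cyclin B, the kinase regulatory subunit (CKS), MAD2, PcnA and kinesin-6 lie higher in all 3 G2 libraries, replication factor C subunit 3 (RFC 3) lies lower, and Aurora kinase and histone H4 overlap between the groups.

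The list of mitotic kinases and spindle checkpoint proteins held 30 tested genes, of which 17 rose and 1 fell, with the same counts adjusted over the list alone. Its median log2 fold change was 0.28 (camera adjusted p = 0.00312; adjusted p = 0.400 with an estimated correlation). Most of the list, 21 genes, carried the description of putative spindle pole proteins, of which 13 rose and 1 fell. MAD2 GL50803_100955, which holds back anaphase while chromosomes are unattached, had 200.2 ± 31.8 FPKM in G1 and 579 ± 19.4 FPKM in G2, a log2 fold change of 1.60 ± 0.10 with an edgeR adjusted p of 1.18e-05. The polo-like kinase GL50803_104150 rose by 0.50 ± 0.06 on the log2 scale. The spindle pole genes GL50803_16013 and GL50803_87149 rose by 1.17 and 1.06, and GL50803_33660 fell by 0.34. Aurora kinase GL50803_5358 had a log2 fold change of 0.05 ± 0.07, the checkpoint kinase TTK GL50803_4405 0.00 ± 0.06, the Wee kinase GL50803_115572 0.20 ± 0.09, BUB3 GL50803_102890 -0.12 ± 0.05 and the Cdc25 phosphatase GL50803_4369 -0.20 ± 0.10, and none of these passed the test. Without G1 replicate 1, BUB3 passed with an edgeR adjusted p of 0.0181 (0.00827 to 0.225 over its alternatives), and the number of falls in the list was 4, against 2 without G2 replicate 1.

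Of 26 kinesins, 15 rose and 5 fell, or 16 and 5 adjusted over the list alone. The median log2 fold change was 0.33 (camera adjusted p = 0.00312; adjusted p = 0.425 with an estimated correlation). Kinesin-6 GL50803_102455, of a family that acts in cytokinesis in other eukaryotes, had 51.3 ± 1.86 FPKM in G1 and 101 ± 1.16 FPKM in G2, a log2 fold change of 1.05 ± 0.05 with an edgeR adjusted p of 3.49e-06. Kinesin-13 GL50803_16945, a microtubule depolymerase, rose by 0.89 ± 0.05. Kinesin-3 GL50803_112846 fell by 1.03 with an SE of 0.06 and had 116 ± 6.68 FPKM in G1 and 54.2 ± 2.09 FPKM in G2. Without G2 replicate 2 or 3 the number of falls was 3.

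Core histones package DNA. Of 11 histone genes, 7 rose and none fell, and 8 rose adjusted over the list alone. Their median log2 fold change was 0.43 (camera adjusted p = 0.00738; adjusted p = 0.683 with an estimated correlation). Both H2A genes, both H2B genes and 3 of the 4 H3 genes rose, by 0.29 to 0.53 on the log2 scale. H2B GL50803_121045 had 1458 ± 77.2 FPKM in G1 and 2007 ± 217 FPKM in G2, with an edgeR adjusted p of 0.00188. The 3 H4 genes had log2 fold changes between 0.04 and 0.05, none of which passed; their mean FPKM was slightly lower in G2, and the sign came from the TMM factors. Copies of one histone are near-identical in many genomes, so the split of reads between them is uncertain. Summed counts scaled with the TMM factors differed by 0.50 ± 0.10 (SE) on the log2 scale for H2B and by 0.04 ± 0.04 for H4, and per plain library total by 0.43 ± 0.09 and -0.030 ± 0.030.

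Genes of DNA replication moved in both directions. Of 27 tested, 5 rose and 7 fell, with the same counts adjusted over the list alone, and the list did not differ from the other genes (camera adjusted p = 0.573). GL50803_16953, described as flap structure-specific endonuclease, an enzyme that trims Okazaki fragments, had 10.3 ± 0.436 FPKM in G1 and 34.04 ± 1.46 FPKM in G2. Its log2 fold change was 1.79 ± 0.08 with an edgeR adjusted p of 3.46e-06. Another gene, GL50803_5488, described as FEN-1 nuclease and chosen after its values were seen, differed less. It had 1821, 2053 and 1273 estimated counts in G1 replicates 1 to 3 and 2196, 2450 and 2344 in G2 replicates 1 to 3. PcnA GL50803_6564, named for the sliding clamp of the replicative polymerases, had 121 ± 25.9 FPKM in G1 and 297 ± 11.4 FPKM in G2, a log2 fold change of 1.37 ± 0.13 with an edgeR adjusted p of 8.55e-05. Replication factor C subunits 3 (GL50803_24636) and 2 (GL50803_9287), parts of the clamp loader, fell by 0.69 and 0.34. Of 18 genes of DNA repair and recombination, 3 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.635). Mre11 GL50803_14493, part of the complex that binds DNA breaks, fell by 0.69 ± 0.08. Of 9 genes of chromosome structure and segregation, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.586). The gene GL50803_16975, described as DNA topoisomerase II, rose by 0.72 ± 0.06, and GL50803_16795, described as topoisomerase II, fell by 0.59 ± 0.06. Of 14 chromatin enzymes, 5 rose and none fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.573), and the histone methyltransferase HMT1 GL50803_9130 rose by 1.15 ± 0.12. Without G1 replicate 2 the number of rises in the replication list was 3, and without G1 replicate 3 the chromatin enzymes had 1 fall.

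High cysteine membrane proteins are surface proteins of Giardia with many cysteine motifs. Of 81 tested, 49 fell and 7 rose, or 52 and 7 adjusted over the list alone. The median log2 fold change was -0.45 (camera adjusted p = 3.86e-10; adjusted p = 0.425 with an estimated correlation). The high cysteine protein GL50803_102180 had 56.8 ± 11.4 FPKM in G1 and 0.624 ± 0.0216 FPKM in G2, a log2 fold change of -6.34 ± 0.22 with an edgeR adjusted p of 2.00e-06. All 8 members with an EGF-like description were measured, and 7 of them fell, among them GL50803_113836 with 40.1 ± 6.17 FPKM in G1 and 12.4 ± 0.991 FPKM in G2 and a log2 fold change of -1.62 ± 0.11. In the other direction, GL50803_25816 and GL50803_11309, both of the description group 1, rose by 1.79 ± 0.14 and 1.51 ± 0.13. The summed counts of the list differed between the groups by -0.09 ± 0.08 (SE) on the log2 scale with the TMM factors and by -0.16 ± 0.07 per plain library total, and GL50803_11309 was its most abundant member. Reads can be shared between related members, so values of single genes in this family are uncertain.

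Variant surface proteins (VSPs) form the coat of the trophozoite, and a single trophozoite displays few of them at a time. Of 189 tested, 7 rose and 33 fell, or 7 and 28 adjusted over the list alone (median log2 fold change -0.01, camera adjusted p = 0.267). This count rested on G1 replicate 1: without that library 68 VSPs rose and 34 fell, and the median was 0.03. Without any 1 other library, 4 to 6 rose and 21 to 30 fell. In G1 replicate 1, 28 VSP genes were at least 2-fold higher than the mean of the other 2 G1 libraries, 1 of them only because it was near 0 in G1 replicate 2. VSP genes held 3.46% of all counts in G1 replicate 1, 2.71% and 2.77% in G1 replicates 2 and 3, and 3.20% to 3.47% in the G2 libraries. The surface protein GL50803_9276 had 749 ± 100.05 FPKM in G1 and 1559 ± 39.7 FPKM in G2 and rose by 1.12 ± 0.09 on the log2 scale, and the VSP GL50803_113357 had 17.8 ± 4.89 FPKM in G1 and 5.50 ± 1.05 FPKM in G2, a log2 fold change of -1.62 ± 0.21 with an edgeR adjusted p of 0.000515. The 8 genes with the VSP-like description belong to both this list and that of the high cysteine membrane proteins.

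**Figure D2:**
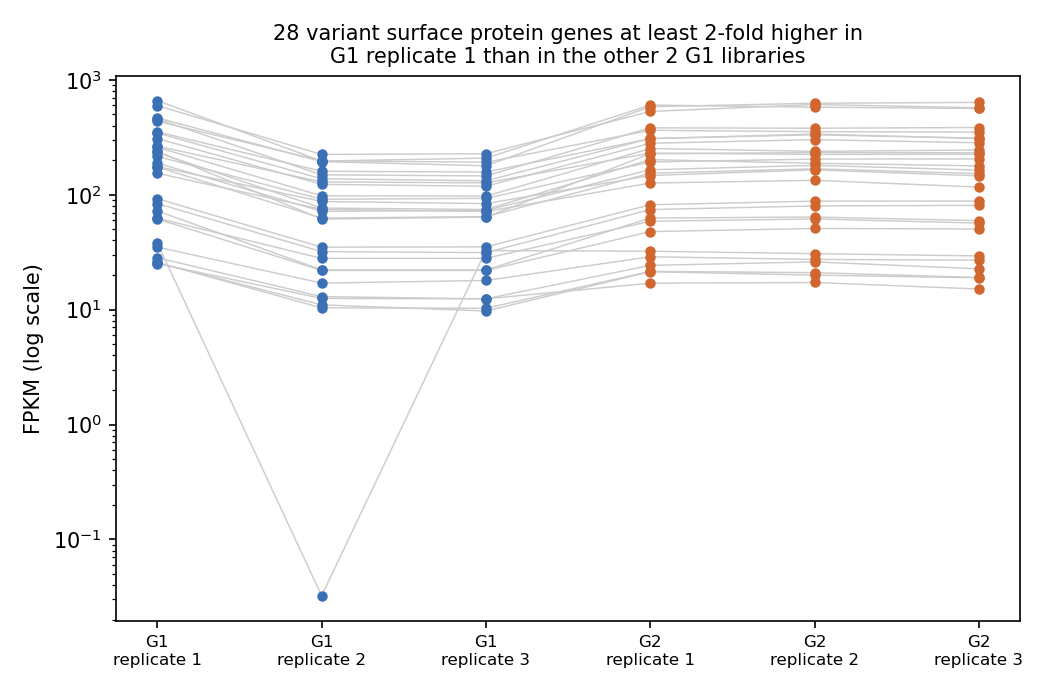
FPKM (log scale) of the 28 VSP genes that were at least 2-fold higher in G1 replicate 1 than the mean of G1 replicates 2 and 3, in each of the 6 libraries; lines join 1 gene. The values in G1 replicate 1 lie near those of the 3 G2 libraries, and GL50803_137613 (chosen after its values were seen) is near 0 in G1 replicate 2 alone.

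Chaperones fold other proteins. Of 43 genes of the chaperone list, 11 rose and 13 fell, or 15 and 13 adjusted over the list alone (camera adjusted p = 0.573). Bip GL50803_17121, the HSP70 chaperone of the endoplasmic reticulum, had 1049 ± 105 FPKM in G1 and 440.3 ± 25.6 FPKM in G2, a log2 fold change of -1.18 ± 0.08 with an edgeR adjusted p of 1.22e-05. The HSP90 genes GL50803_13864 and GL50803_98054 fell by 0.66 and 0.73, and the protein disulfide isomerase PDI5 GL50803_8064, which forms disulfide bonds, fell by 0.72. Of 21 cathepsins and other cysteine proteases, which digest proteins, 10 fell and none rose, also when adjusted over the list alone. Their median log2 fold change was -0.22 (camera adjusted p = 0.00312; adjusted p = 0.425 with an estimated correlation). The cysteine protease GL50803_114915 fell by 0.70 ± 0.09, and the cathepsin L-like gene GL50803_137680 by 0.41 ± 0.06. The number of falls among the proteases was 6 without G2 replicate 1 and 5 without G2 replicate 3, 1 of them rose without G1 replicate 1, and 7 chaperones rose without G1 replicate 2 or G2 replicate 3.

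Of 14 tubulin and tubulin-folding genes, 1 rose and 5 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.573). The 3 beta-tubulin genes, whose products pair with alpha-tubulin in microtubules, fell by 0.55 to 0.58 on the log2 scale. Of these, GL50803_101291 had 1857 ± 165 FPKM in G1 and 1186 ± 46.8 FPKM in G2, with an edgeR adjusted p of 0.000289. Both genes described as tubulin-specific chaperone D fell, GL50803_15906 by 0.95 and GL50803_10145 by 0.52. In the axoneme, dynein and flagellar transport list, 20 of 61 genes rose and 7 fell, or 21 and 8 adjusted over the list alone (camera adjusted p = 0.188). The dynein regulatory complex gene GL50803_16540 had 42.7 ± 2.17 FPKM in G1 and 119 ± 4.40 FPKM in G2 and rose by 1.55 ± 0.05. Giardins are structural proteins of the ventral disc, by which the trophozoite attaches. Of 25, 8 rose and 4 fell, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.594), and alpha-10 giardin GL50803_5649 rose by 0.61 ± 0.07. Of 10 actin and cytokinesis genes, 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.423), and the actin related gene GL50803_8726 rose by 0.94 ± 0.05. Tubulin genes had 3 rises without G1 replicate 1 and 2 without G1 replicate 2 or G2 replicate 1, and the axoneme list had 4 falls without G1 replicate 3 and 3 without G2 replicate 1 or 3. The actin list had 1 fall without G2 replicate 2 or 3 and 3 rises without G2 replicate 3.

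NEK kinases form an expanded kinase family in Giardia. Of 179, 47 rose and 18 fell, or 49 and 19 adjusted over the list alone (camera adjusted p = 0.417), and GL50803_95593 had 292 ± 31.8 FPKM in G1 and 774 ± 18.2 FPKM in G2 and rose by 1.48 ± 0.08. Of 244 genes of the ankyrin repeat family, 73 rose and 37 fell, or 80 and 41 adjusted over the list alone (camera adjusted p = 0.230), led by GL50803_16534 with a rise of 1.39 ± 0.06. Among 52 proteasome and ubiquitin genes, 10 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.573), and the ubiquitin hydrolase GL50803_16090 rose by 1.63 ± 0.07. Encystation genes, which mark cells turning into cysts, gave 2 rises and 3 falls among 16, also when adjusted over the list alone (camera adjusted p = 0.573). The cyst wall proteins 1 (GL50803_5638), 2 (GL50803_5435) and 3 (GL50803_2421) had log2 fold changes of -0.04 ± 0.06, 0.09 ± 0.09 and -0.04 ± 0.09, none of which passed, though the second reached 0.17 with an edgeR adjusted p of 0.0420 without G1 replicate 1 (0.0420 to 0.965 over its alternatives). The glucosamine-6-phosphate deaminase GL50803_8245 fell by 0.80 ± 0.05. Of these counts, the falls among proteasome and ubiquitin genes numbered 19 without G1 replicate 1, those among NEK kinases 11 and among the ankyrin repeat family 24 without G2 replicate 3, and no encystation gene rose without G1 replicate 2 or G2 replicate 3 and 1 without G1 replicate 3 or G2 replicate 2.

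Among genes of protein synthesis, 9 of 71 ribosomal proteins rose and 8 fell, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.953). Of 48 genes of ribosome biogenesis and RNA polymerases, 15 rose and 5 fell, or 18 and 5 adjusted over the list alone (camera adjusted p = 0.134), with the nucleolar GTPase GL50803_16498 up by 0.73 ± 0.05. Translation factors and tRNA synthetases gave 11 rises and 7 falls among 48, also when adjusted over the list alone (camera adjusted p = 0.586). In energy metabolism, 9 of 23 genes of glycolysis and fermentation rose and 2 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.213, and 0.0332 without G1 replicate 1 in a range of 0.0332 to 0.722 over its alternatives). Fructose-bisphosphate aldolase GL50803_11043 rose by 0.44 ± 0.05, and pyruvate-flavodoxin oxidoreductase GL50803_114609 fell by 0.92 ± 0.09. In the arginine dihydrolase pathway, which yields energy from arginine, arginine deiminase GL50803_112103 fell by 0.24 ± 0.07, a call lost without any 1 of the G2 libraries, and the other 3 genes did not pass, also when adjusted over the list alone (camera adjusted p = 0.859). Redox and oxygen defence genes gave 5 rises and 8 falls among 21, and vesicle transport genes 9 and 9 among 59, with the same counts adjusted over the list alone (camera adjusted p = 0.417 and 0.573). Clathrin heavy chain GL50803_102108 fell by 0.66 ± 0.07. Without G1 replicate 1, falls numbered 22 among ribosomal proteins, 11 among translation factors and 15 among vesicle transport genes. Rises among ribosomal proteins numbered 2 to 6 without any 1 library other than G2 replicate 1, those among translation factors 5 without G2 replicate 3 and those in glycolysis 5 without G2 replicate 2, and falls in ribosome biogenesis 3 without G1 replicate 3 or G2 replicate 1 or 3.

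**Figure D3:**
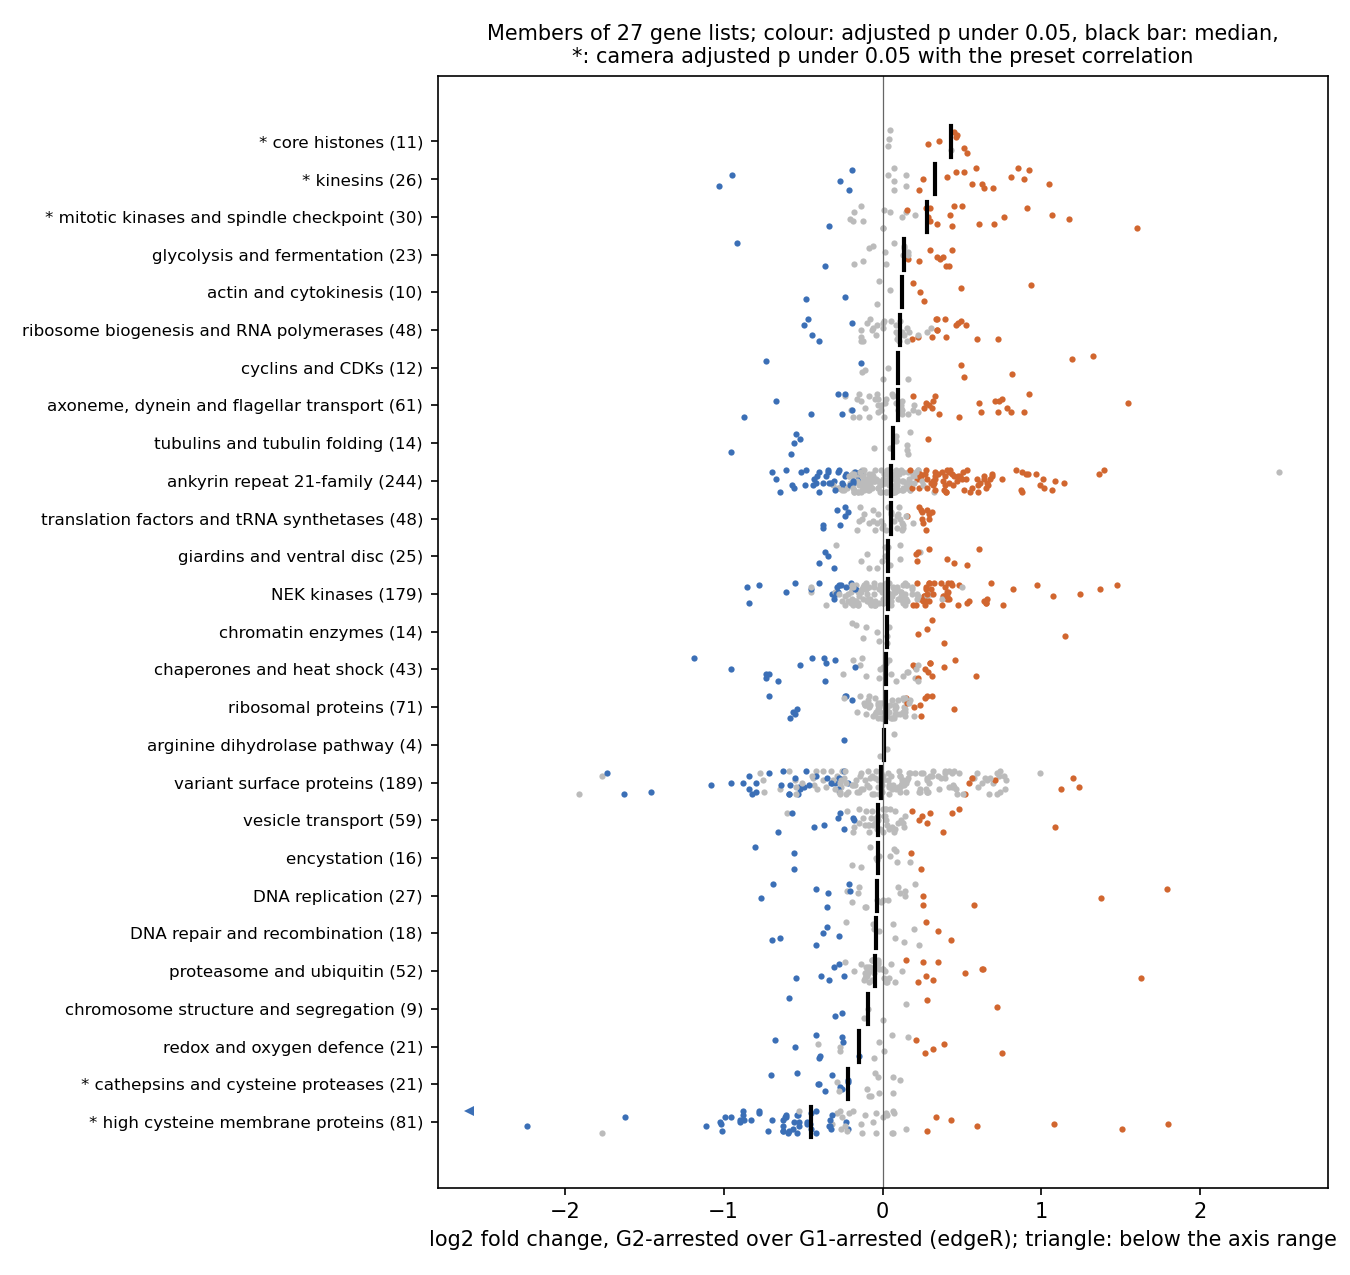
Log2 fold change (G2 over G1, horizontal axis) of the members of the 27 lists, ordered by median (black bar), with the number of tested members in brackets. Orange and blue points rose and fell at an edgeR adjusted p under 0.05, grey points did not pass, and the 5 lists with an asterisk, 3 higher and 2 lower, passed camera with the preset correlation; the triangle is GL50803_102180 at -6.34.

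Of the 27 lists, 5 passed camera with the preset correlation and none with an estimated correlation. For the mitotic kinases and spindle checkpoint proteins the estimated correlation was -0.0226, below the preset 0.01. A higher correlation between members therefore cannot account for the loss of that list. For the other lists that passed, it lay above the preset value, between 0.0757 (kinesins) and 0.458 (core histones). What else made the lists fail in that setting was not tested. The adjusted p of these 5 lay between 2.96e-11 and 0.0275 in the 22 settings that kept the preset correlation or used fry. In 6 lists (DNA replication, tubulins, ribosomal proteins, proteasome, chaperones and the arginine dihydrolase pathway) the median and the mean log2 fold change differed in sign.

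Of the largest changes outside these groups, GL50803_8524, described as a transitional endoplasmic reticulum ATPase, rose by 1.44 ± 0.12. The hypothetical genes GL50803_14647 and GL50803_8505 rose by 2.37 ± 0.10 and 1.94 ± 0.10. Rises of the 5S RNA genes GL50803_r0006 and GL50803_r0015 rested on 5 and 8 estimated counts summed over the G1 libraries and 21 and 25 over the G2 libraries. These are ratios of 4.38 (95% exact binomial interval 1.61 to 14.9) and 3.26 (1.43 to 8.37), and the intervals cover counting error only. The first call was lost without G1 replicate 2 or 3 or without G2 replicate 1 or 3, and the second without G1 replicate 3 or G2 replicate 1. Among the falls, the MCT-1-like gene GL50803_13897 had 178 ± 36.4 FPKM in G1 and 68.5 ± 6.01 FPKM in G2 and a log2 fold change of -1.31 ± 0.14, and the CEGP1 gene GL50803_17120 -1.24 ± 0.08. The VSPs GL50803_92835 and GL50803_112331 and the high cysteine protein GL50803_17212 fell from levels under 3 FPKM. The phospholipid-transporting ATPase GL50803_137725 fell by 4.19, but G1 replicate 3 held 0.826 FPKM against 19.8 and 17.9 FPKM in the other 2 G1 libraries, and its call was lost without G2 replicate 2 (edgeR adjusted p = 0.0507) and in all 7 limma settings, in a range of 2.77e-06 to 0.0985 over its alternatives. The hypothetical gene GL50803_38432 reached 119.99 FPKM in G1 replicate 3 alone, and its log2 fold change of -6.50 became -1.93, no longer past the threshold, without that library. Its call was also lost without any 1 G2 library and in the limma settings. The hypothetical gene GL50803_21570 fell from 56 to 7 summed counts, a ratio of 7.66 (95% exact binomial interval 3.48 to 19.9).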

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

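Of the alternatives here, 3 were chosen only after the results were seen: leaving out genes that differed at least 8-fold within a group, leaving out tRNA and rRNA genes, and library totals without scaling factors. They moved no count of genes or lists by more than 1.5 times. Over 22 settings, 161 genes that the naming rule allowed and 3 cyst wall proteins gave 3306 of 3592 values with the direction and side of the threshold kept, 137 calls lost, 43 gained and no called direction turned, and 127 genes kept theirs in every setting. The number of genes at least 2-fold apart was 69 (51 higher, 18 lower) in limma with a pseudocount of 5, which by construction shrinks the change of low genes. It was 141 (75 and 66) in limma with a pseudocount of 1 and 193 (87 and 106) with 0.1, so it fell as the pseudocount grew. Without the trend, at a pseudocount of 1, it was 135 (72 and 63), so removing the trend changed it little. After quantile normalization it was 132 (36 lower), and 52 were lower after median-of-ratios scaling. Other causes of the gap between limma and edgeR were not tested. In edgeR at a mean FPKM of at least 10, with 4598 genes tested, 101 genes were at least 2-fold apart (27 lower). At an adjusted p under 0.01, 1252 genes changed, 439 of them lower and 50 at least 2-fold lower. Without 1 library, 1502 to 2387 genes changed, 925 to 1344 higher and 577 to 1043 lower. Of those, 172 to 251 changed at least 2-fold, 95 to 121 higher and 77 to 130 lower, and 5 to 6 lists passed. With an estimated correlation 0 of the 27 lists passed, and with fry, which does not compare a list with other genes, 18 did. The DNA replication list, with a median of -0.035, reversed under fry, whose statistic was upward where that of camera was downward; its fry adjusted p was 0.0372, in a range of 0.0372 to 0.722. DESeq2 called 2049 genes. With the replicate number as a block, limma called 774 genes higher, against 886 without the block, and edgeR 1857 in all, against 2032. Same-numbered samples had deviations correlated at r = 0.127, 0.0926 and -0.0757 across genes, and G1 replicate 3 correlated best with G2 replicate 2 (0.117). These values give no clear sign that the numbers pair the samples. With 3 libraries per group they cannot exclude a pairing. Depth limited the genes with few counts, such as the 5S RNA genes, to the wide intervals given with them.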

Other observations

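Of the tests in this part, the removal of trends and the summed counts with the TMM factors for the high cysteine membrane proteins were planned before their results were seen, and all the other tests, groupings and named genes were chosen only afterwards.

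Of 8 genes described as subunits of the TCP-1 chaperonin, the complex that folds tubulin and actin, 6 rose and none fell. Their summed counts, scaled to a common library total with the TMM factors (CPM), were 5130.3 ± 132 in G1 and 6110.6 ± 51.4 in G2 (mean ± SD, n = 3), a log2 difference of 0.25 ± 0.02 (SE). Of 9 genes described as BiP, HSP90, cytosolic HSP70 or protein disulfide isomerase, 8 fell, and their summed CPM went from 23662 ± 1148 to 15911 ± 467, a log2 difference of -0.57 ± 0.05. The tubulins did not move together. Beta-tubulin CPM summed to 6489.9 ± 500.0 in G1 and 4398 ± 176 in G2, while the sum of the 2 alpha-tubulin genes, neither of which passed the test, differed by 0.10 ± 0.07 on the log2 scale. Estimated counts of beta-tubulin were 0.835 ± 0.0275 of those of alpha-tubulin in G1 and 0.528 ± 0.0172 in G2. The ratio needs no scaling between libraries, and an exact permutation test of 3 against 3 libraries cannot give a p under 0.1. In the replication machinery, 3 of 5 replication factor C genes fell and 1 of 6 MCM genes fell.

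Product descriptions shared by several tested genes formed 39 families, which were tested with camera at the preset correlation. Of 36 genes described as coiled-coil proteins, 20 rose and 1 fell (median log2 fold change 0.28, adjusted p = 5.62e-05; adjusted p = 0.217 with an estimated correlation). Of 6 genes described as Ser/Thr protein kinase, 4 rose and none fell (adjusted p = 0.0368; 0.545 with an estimated correlation). In total 8 families passed at the preset correlation and none with an estimated one. Of the other 6 that passed, spindle pole proteins and 5S RNA were higher in G2, and 3 high cysteine families and the putative VSPs were lower. The 5S RNA genes GL50803_r0006 and GL50803_r0015 held only 1 to 10 estimated counts per library, in libraries made from poly(A)-selected RNA. The result of that family is therefore uncertain.

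Of the 125 VSP genes with a mean of at least 10 CPM, 28 were at least 2-fold higher in G1 replicate 1 than the mean of the other 2 G1 libraries and 0 lower, against 5 of 3937 other genes higher, and the median of the 28 stood 1.36 above those libraries but 0.14 above the G2 libraries on the log2 scale. Of the 28, 27 were called higher in G2 by edgeR without G1 replicate 1, and 1 with it; the exception, GL50803_137613, entered only because it was near 0 in G1 replicate 2. Reads traded among VSP copies would leave the share of VSP counts level, and it was 0.727 percentage points above the 2.74% of the other G1 libraries, with an SD of 0.148 among the G2 libraries. A G2 library under a G1 label was argued against by 2285 other genes, whose median position in this library was 0.0801 ± 0.0117 (bootstrap SE) on a scale from 0, the other G1 libraries, to 1, the G2 libraries. The summed FPKM of the 28 genes was 6084 in G1 replicate 1, 2340 and 2345 in G1 replicates 2 and 3, and 5534 to 5745 in the G2 libraries. For these genes, G1 replicates 2 and 3 were therefore the libraries apart from the rest. A different VSP makeup, through switching or history, of the material behind G1 replicate 1 or behind G1 replicates 2 and 3 may account for the block. Neither was tested.

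Most high cysteine membrane proteins were lower in G2, with a list median of -0.45. Encysting cells in the G1 cultures would bring cyst wall proteins. The median of the 3 such genes was -0.036 (SE of their mean 0.0469, taking the genes as independent). Of the 16 genes of the encystation list, however, 2 rose and 3 fell. The falls, of GL50803_8245 by 0.80 and of GL50803_10829 and GL50803_14651 by 0.56 each, have the direction that encysting cells in G1 would give. The markers therefore did not settle that explanation. Removing the trend of other genes with length and level left the high cysteine list at -0.46 (bootstrap SE 0.0858). Reads traded between copies would keep the list's summed counts level, which they were within their spread with the TMM factors (-0.091 ± 0.080), as had been set in advance for that explanation, but not per plain library total (-0.16 ± 0.07). It was left open only afterwards, because the sums of the description families went both ways: 8 of 10 were lower in G2 by more than 2 SE (9 per plain total), against trading within families alone, and Group 1, with 33.8% of the list's counts, was higher by 0.54 ± 0.11. Trading across families, and an effect of the phase or of either drug, remain possible and untested. If the groups had different drugs, the design cannot separate phase from drug.

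In 24 genes with at least 100 counts in some library, counts differed at least 8-fold between libraries of one group, and 17 of the 24 are hypothetical proteins. Among examples chosen after their values were seen, GL50803_5800 had 18032, 17225 and 17799 counts in G1 replicates 2 and 3 and G2 replicate 2 and 0 in the other 3 libraries, and Sec13, GL50803_137698, a coat protein of transport vesicles, had 0 in G2 replicate 1 and 4772 to 5768 elsewhere. An assignment of all the missing reads to genes within 2 places in the table was argued against for 8 of the 24, these examples included, since the gains of those genes plus 2 SE stayed below the loss, at 2.50% of it for GL50803_5800 and 15.2% for Sec13. For the other 16 it stays open, and a partial assignment stays open for all 24. A gene with mirrored counts within 2 places stood beside 6 of the 24, in 5 pairs. Random sets of genes that did not switch in this way had a median of 4 and a 95th percentile of 7. Sec13 was among the 6: the adjacent gene GL50803_20728 held 169 counts in G2 replicate 1 and 2 to 5 elsewhere (r = -0.985). No biological explanation was tested, and 4 of these genes are among the 2032 called.

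The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 2032 genes in the edgeR test and the highest of the other splits 4.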
